A study of Mus musculus with 2 samples.

How the data were processed

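The series holds 2 single-cell RNA libraries of sorted CD45+ cells of mouse liver, 1 from untreated and 1 from ConA-treated mice, made with 10x Genomics chemistry. The labels' protocols name a 3' kit, version 3.1, which was not checked against the barcodes because no barcode list was at hand. The deposited matrices hold raw UMI counts per gene and barcode, written by software version 8.0.1 per the file headers, whereas the submitters' processing notes name Cell Ranger 6.0.1, Seurat 4.3.0 and the mm39 genome. No barcode in the files had fewer than 500 UMIs, so barcodes had been filtered before deposit. Each library has 33696 genes, given by the symbol that the feature files pair with an Ensembl identifier. No coordinates were used, because the annotation at hand is of another build.

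Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs, which left 17632 of 18088 untreated and 17767 of 18762 ConA barcodes. Doublets were scored within each library against simulated doublets by nearest neighbours, the Scrublet method written anew, and the highest-scoring cells were removed at 0.8% per 1000 barcodes times the share of pairs that join different clusters. This removed 2274 cells (12.9%) from the untreated and 2375 (13.4%) from the ConA library.

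Both libraries were clustered together without integration. Counts per 10000 were log-transformed, 2000 variable genes and 30 principal components were taken, and a shared-neighbour graph of 20 neighbours was divided by the Leiden method at resolution 1. T, NK and innate lymphoid clusters and mononuclear phagocyte clusters were clustered again in the same way. A cluster was named "-like" after the type, of 27 with marker lists, whose markers stood highest above the other clusters, when at least 3 of these markers were 2-fold higher than in the rest. It stayed unnamed when its 10 leading genes held more markers of another type, or when its median depth was under 1/3 of that of the library most of its cells came from and none of those genes was a marker of its own. Zbtb16-high T is a descriptive name given only where T, NK and innate lymphoid clusters were clustered again. It covers T clusters without another name whose Zbtb16 level was at least 2 times that of all T, NK and innate lymphoid cells. Cluster 15 had fewer than 3 markers at 2-fold in the first clustering, so it stayed unnamed and the rule did not reach it. Classical monocyte, monocyte-derived macrophage and Kupffer markers were joined into a single class. Markers, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The exact naming rule, the joined class, the Zbtb16 rule, the estimate of free RNA and 3 alternatives were set after the clusters had been seen. In the feature files 4 gamma-delta T markers and 2 list members go under other symbols. The list members were found by their present symbols, and Aldoa was left out because more than 1 gene identifier carries the symbol.

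UMIs were summed per class and library and expressed as CPM of the class's UMIs. With 1 library per group no test between groups was made and no p-value was computed. Log2 ratios have exact conditional Poisson 95% intervals and shares of cells exact Clopper-Pearson intervals, both for counting error only. Genes were compared in classes with at least 100 cells in both libraries, and the 6 classes with the most cells were described in full. Named genes were the 10 per direction with the largest log2 ratio of CPM plus a constant of 5 CPM, among genes with at least 50 CPM in 1 library, at least 100 UMIs and a 2-fold ratio. Mitochondrial, ribosomal and receptor segment genes, markers of the class, unnamed gene models and genes at less than 5% of their level in another class of the same library, which could be free RNA, were left out. To these were added the members of the lists with the largest ratios.

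The 23 gene lists covered cytotoxic effector, checkpoint and exhaustion, naive and circulating T, tissue residency, Treg suppression, T helper cytokine and regulator, NKT identity, interferon-stimulated, interferon-gamma-induced, MHC class II, inflammatory, regulatory and tolerance-associated, Kupffer cell identity, lipid-associated macrophage, complement and efferocytosis, immature neutrophil, B cell activation, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, dissociation stress, free hepatocyte RNA and free red cell RNA genes. A list's value is the median log2 ratio, with the constant of 5 CPM, of its members with at least 10 CPM in 1 library. Its interval comes from 1000 Poisson resamples of the counts, and its percentile from 10000 random lists of the same size matched on mean expression in 20 bins. Detection shares were taken after thinning each cell to 1000 UMIs, leaving out shallower cells. The free share of a class's UMIs was estimated as its level of S100a8 and S100a9 (Igkc for neutrophils) over that of all cells of the library. It is an upper estimate where cells of the class express these genes.

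Alternatives changed the UMI minimum, the mitochondrial limit, the doublet removal, the resolution, the joint clustering, the naming by clusters, the scaling, the weighting of cells, the constant, the minimum for list members and the thinning. On simulated data the ratio of B-like cells was tested over 3617 genes, 200 of them changed by more than 2-fold. Of these 99.5% were recovered at the 2-fold limit, with 0 unchanged genes called, and the intervals covered 95.4% of the true values. For NK-like cells, over 3862 genes, 100% were recovered and the intervals covered 94.7%. A list with a true log2 ratio of -2 came out at -1.92 in B-like and -1.73 in NK-like cells. The simulated counts were Poisson draws from a single profile, the model that the intervals assume. They thus check the calculation only, and not differences between mice, preparations, free RNA or clusters. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.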

Results

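Droplet-based single-cell RNA sequencing was performed on CD45+ cells from mouse liver, enriched on a Ficoll density gradient and sorted by flow cytometry. The series holds 2 libraries, 1 from untreated C57BL/6J mice and 1 from mice given concanavalin A (ConA), a plant lectin that activates T cells. ConA was injected intravenously at 10 mg/kg, 1 time a week over 3 weeks, a schedule the labels describe as a model of immune tolerance. The number of mice behind each library is not given in the sources used here. The untreated library held 18088 barcodes with 71289226 UMIs and the ConA library 18762 barcodes with 73589264 UMIs. After filtering and removal of predicted doublets, 15358 untreated and 15392 ConA cells remained, with medians of 2933 and 3259 UMIs.

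The comparison of the libraries asks which immune cells the liver held after repeated ConA and what they expressed. With 1 library per group there is no replicate check, so each difference describes these libraries and not the treatment. Paired values give the untreated library first and the ConA library second, and log2 ratios are ConA over untreated. The 95% intervals cover counting error only. They are exact Clopper-Pearson intervals for shares and exact conditional intervals for ratios of counts. Levels are counts per 1000000 UMIs of the class (CPM).

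Neutrophil-like cells made up 17.5% (95% interval 16.9 to 18.1) of the untreated library and 3.18% (2.91 to 3.47) of the ConA library, a log2 ratio of -2.46 (-2.60 to -2.32). Monocyte and macrophage-like cells made up 16.6% and 2.83%, a log2 ratio of -2.55 (-2.70 to -2.41). Zbtb16-high T cells, named after the gene of PLZF, the transcription factor of innate-like T cells such as NKT cells, were 2.40-fold more frequent in the ConA library (4.20% and 10.1%, log2 ratio 1.26 (1.13 to 1.40)). The class does not hold all cells with high Zbtb16. The gamma-delta T-like cluster T15 had 4.29 times the Zbtb16 level of all T, NK and innate lymphoid cells. Unnamed cluster 15 had Zbtb16 among its leading genes. CD8 T-like cells were 11.9-fold more frequent in the ConA library (0.729% and 8.67%, log2 ratio 3.57 (3.29 to 3.86)). This count leaves out cluster T13 (220 untreated and 172 ConA cells), which scored highest for CD8 T markers. Its 10 leading genes held no CD8 T marker and 1 of another type, so it was counted among other T, NK and innate lymphoid cells. CD4 T-like cells outside the naive and regulatory classes numbered 8 and 471, and gamma-delta T-like cells 5 and 374. Together these last 3 classes made up 0.814% and 14.2% of the cells. ILC1-like cells, innate lymphocytes resident in the liver, were 2.36% and 4.92%.

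B-like cells were the most numerous class in both libraries (26.7% and 21.7%, log2 ratio -0.29 (-0.36 to -0.23)), followed in the ConA library by naive T-like cells (8.86% and 12.5%, log2 ratio 0.50 (0.40 to 0.60)). NK-like cells (6.05% and 5.80%) and regulatory T (Treg)-like cells (1.51% and 1.43%) had log2 ratios of -0.06 (-0.20 to 0.07) and -0.08 (-0.35 to 0.19), so no difference was detectable at this depth. The Treg-like ratio depended on the setting and was -1.12 with up to 20% mitochondrial UMIs and 0.78 by marker scores. Plasmacytoid dendritic cell (pDC)-like cells were 3.01% and 3.56%, cross-presenting cDC1-like cells 0.417% and 1.25%, cDC2-like cells 1.57% and 1.35% and non-classical monocyte-like cells, which patrol vessels, 1.95% and 1.14%. The cDC1-like log2 ratio of 1.59 was 0.88 without doublet removal and 0.38 by marker scores. The cDC2-like ratio of -0.22 became 0.27 with fewer doublets removed. Erythroid-like cells, which a CD45 sort and a Ficoll gradient should remove, were 0.873% and 6.07%. Plasma-like cells numbered 5 and 207, but 89 and 434 before doublet removal. Basophil or mast-like cells numbered 0 and 120, but 90 and 170 before it, and hepatocyte-like cells 0 and 62, but 156 and 127, so the differences in these rare classes depend on doublet removal. 

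**Figure D1:**
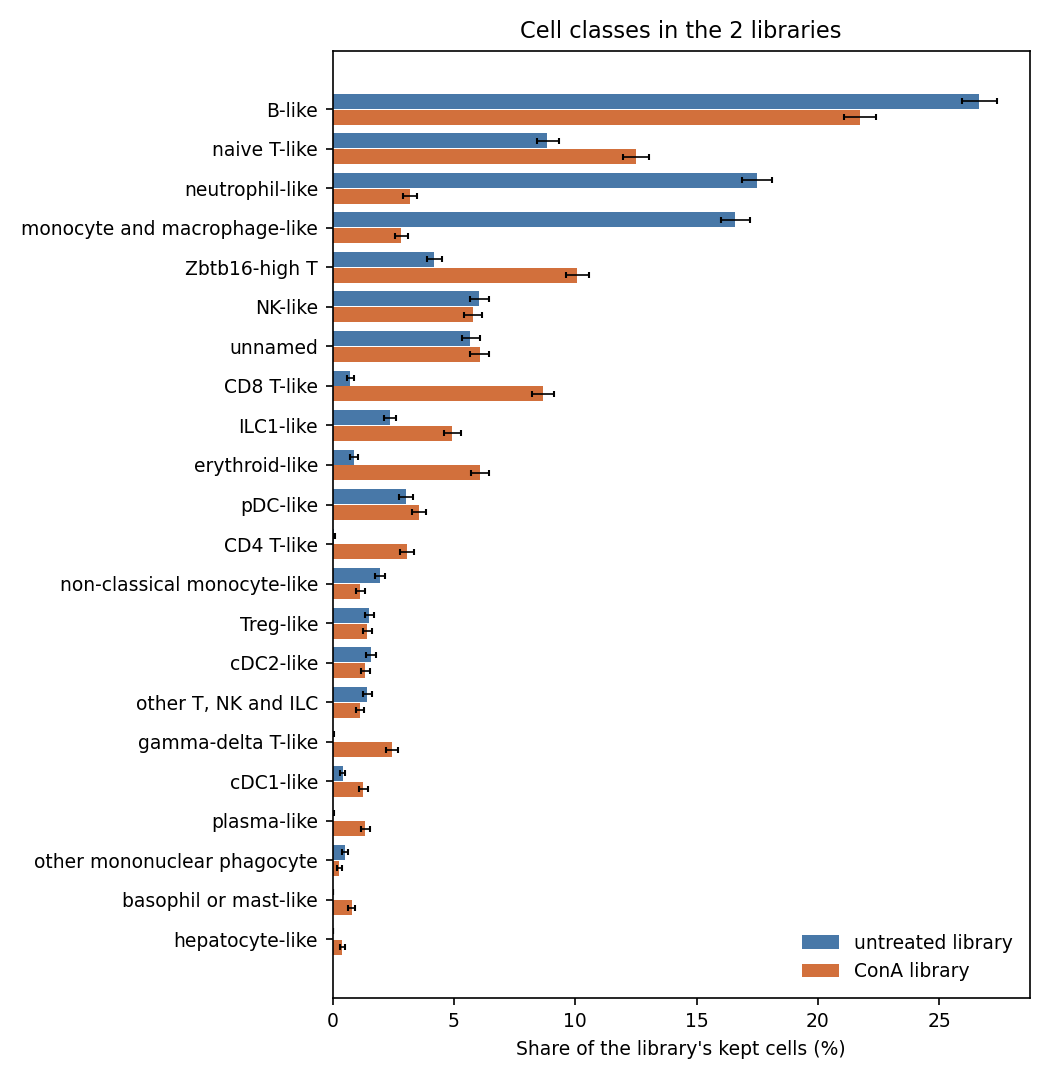
Share of each library's kept cells (%) in each cell class, with 95% Clopper-Pearson intervals that cover counting error only. Neutrophil-like and monocyte and macrophage-like cells have larger shares in the untreated library, and Zbtb16-high T, CD8 T-like, CD4 T-like and gamma-delta T-like cells in the ConA library.

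Because a lower share of the large phagocyte classes raises every other share, lymphocytes were also compared among T, NK and innate lymphoid cells alone. There Zbtb16-high T cells were 16.7% and 20.2%, CD8 T-like cells 2.89% and 17.3%, naive T-like cells 35.1% and 25.0%, NK-like cells 24.0% and 11.6%, ILC1-like cells 9.35% and 9.85% and Treg-like cells 5.99% and 2.86%. Summed over all these cells, whatever their class, most markers of CD8, CD4 and gamma-delta T cells differed far less than the classes, though several are shared with naive T or NK cells. The CD8 T markers Cd8a, Cd8b1, Gzmk, Eomes and Cd160 were 1.57, 1.35, 2.77, 0.930 and 1.02 times as high in the ConA library, and the CD4 T markers Cd4, Cd40lg, Icos and Izumo1r 1.16, 1.71, 1.93 and 0.930 times. Of the gamma-delta genes, Trdc, Trgc1, Trgc2, Trgc4 and Trdv4 were 1.38, 2.05, 1.04, 1.12 and 3.43 times as high and the scavenger receptor gene Scart1 25.1 times (4.09 and 103 CPM). Of the Treg markers other than Foxp3, Il2ra, Ikzf2, Ctla4 and Tnfrsf18 were 1.235, 1.34, 1.46 and 0.703 times as high. Most thus did not follow the lower Treg-like share. However, Ctla4 was also a leading gene of CD4 T-like cluster T11 and CD8 T-like cluster T17, and Ikzf2 of cluster T13. Markers shared with other classes cannot decide whether the Treg-like share was lower. Among mononuclear phagocytes, monocyte and macrophage-like cells were 78.9% and 41.2%, non-classical monocyte-like cells 9.25% and 16.7%, cDC1-like cells 1.98% and 18.3% and cDC2-like cells 7.46% and 19.7%. The Ficoll gradient, which separates granulocytes and red cells by density, the CD45 sort and the minimum of 500 UMIs all precede these counts and can set the neutrophil and erythroid shares.

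The excess of CD8, CD4 and gamma-delta T-like cells depended in size on how cells were assigned. At resolution 2 it was 8.67-fold, with CD4 T-like cells numbering 161 and 658. With each cell given the class of its highest marker score, without clusters, the 3 classes made up 4.32% and 17.1%, a 3.95-fold excess, with CD8 T-like cells numbering 242 and 1155, CD4 T-like cells 307 and 869 and gamma-delta T-like cells 115 and 607. Of all cells, 74.4% lay in the 31 of 46 clusters that took at least 90% of their cells from 1 library, and such a cluster may be the library rather than a cell type. When 163 genes were left out of the clustering, chosen after the data were seen as genes that differ between the libraries in most classes plus the interferon lists, 17.5% of cells lay in such clusters, and 16 of 17 log2 share ratios stayed within their intervals. Unnamed clusters held 5.68% and 6.06% of the cells. They were clusters 15, 17 and 25. Cluster 15 (1.56% and 3.25% of the libraries) was led by Atp8a2, Abtb3 and Zbtb16. Cluster 17 (622 untreated and 35 ConA cells) was led by the pancreatic enzyme genes Ctrb1, Cela2a and Prss2. These genes were 284, 219 and 199 CPM in the untreated unnamed cells. Cluster 25 (10 untreated and 396 ConA cells) was led by Iglc1, Ighg2b and Mki67. Clusters 17 and 25 were shallow, with median depths of 655 and 685 UMIs, against 2933 and 3259 over all kept cells of the libraries.

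Interferon-stimulated genes were lower in the ConA library in each of 12 immune cell classes with at least 100 cells per library. The list's median log2 ratio was -3.86 (-4.10 to -3.61) in neutrophil-like cells, -3.49 (-3.82 to -3.32) in cDC2-like cells, -2.96 (-3.12 to -2.85) in monocyte and macrophage-like cells, -2.91 (-3.15 to -2.83) in B-like cells and -1.55 (-1.76 to -1.39) in Treg-like cells, the smallest of 12 classes. All measured members, 15 or 16 of 16 per class, were lower in each of the 12 classes. Each median lay at percentile 0 of 10000 random lists matched on expression, which describes these libraries only. Ifit3, an antiviral gene induced by interferon, was 1209 and 3.67 CPM in neutrophil-like, 353 and 4.83 in B-like and 91.9 and 4.77 in NK-like cells. The ubiquitin-like modifier gene Isg15 was 2412 and 107 CPM in neutrophil-like and 1581 and 91.0 in monocyte and macrophage-like cells. Irf7, the transcription factor that amplifies type I interferon, was 840.3 and 76.4 CPM in monocyte and macrophage-like and 194 and 11.2 in B-like cells.

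Genes induced chiefly by interferon-gamma differed less. Their median log2 ratio was -2.10 (-2.47 to -1.94) in neutrophil-like cells, -1.09 (-1.28 to -0.99) in monocyte and macrophage-like cells and -0.19 (-0.45 to -0.09) in NK-like cells. The guanylate-binding protein gene Gbp2 was 226 and 20.2 CPM in neutrophil-like cells, and Cxcl10, a chemokine that draws CXCR3-positive T cells, was 455 and 92.5 CPM in monocyte and macrophage-like cells. After thinning to 1000 UMIs per cell, Ifit3 was detected in 60.5% (58.6 to 62.5) and 0.210% (0.00531 to 1.16) of neutrophil-like cells, with 157 and 12 shallower cells left out. The unthinned shares were 78.6% and 0.818%. Erythroid-like cells, taken as background, gave 4.03% and 0%, with median depths of 3659 and 2894 UMIs against 2510.5 and 3080 in neutrophil-like cells. RNA estimated as free in the droplets made up 9.98% and 11.4% of the UMIs of B-like cells and 6.47% and 12.3% of those of monocyte and macrophage-like cells. Of the Isg15 level of B-like cells (183 and 13.6 CPM), 105 and 8.02 CPM was estimated as free RNA, and of their Ifit3 level 46.0 and 1.05 CPM.

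**Figure D2:**
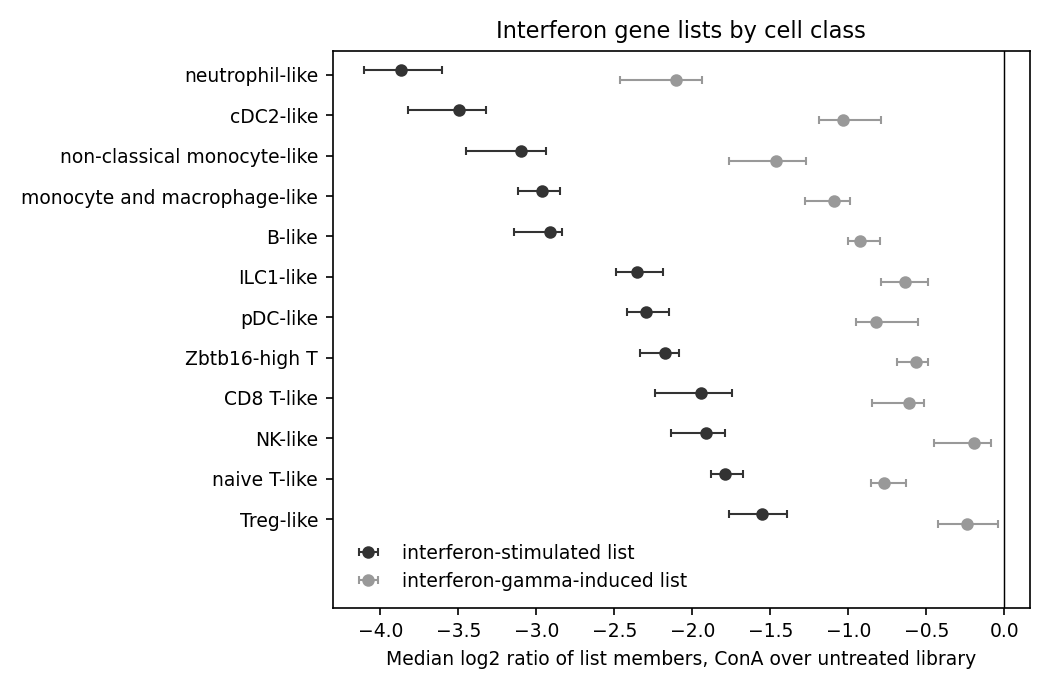
Median log2 ratio (ConA over untreated) of the interferon-stimulated and interferon-gamma-induced lists in each cell class, with 95% intervals from resampled counts that cover counting error only. Medians of the interferon-stimulated list run from -3.86 in neutrophil-like cells to -1.55 in Treg-like cells, below those of the other list in each class.

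In neutrophil-like cells, genes of the immature neutrophil list that encode secondary granule proteins, made during maturation in the bone marrow, were higher in the ConA library. The lactoferrin gene Ltf was 98.1 and 2595 CPM, a log2 ratio of 4.73 (4.61 to 4.84), the granule protein gene Ngp 542 and 9529 CPM and the cathelicidin gene Camp 712 and 10910 CPM. Cebpe, the transcription factor that drives this stage, was 7.95 and 104 CPM and Itgb2l 9.69 and 114. Golim4, Zmpste24, Adpgk, Fmnl2 and Olfml2b were the other genes with the largest excess, with log2 ratios from 3.08 to 4.07. The list of immature neutrophil and suppressor granulocyte genes had a median log2 ratio of 0.44 (0.38 to 0.50), with 10 of 15 members higher (percentile 99.9 of random lists), while its member Wfdc17 was 2418 and 668 CPM.

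Inflammatory mediators were lower in the ConA neutrophil-like cells. The chemokine gene Cxcl2, which recruits further neutrophils, was 3017 and 429 CPM (log2 ratio -2.81 (-2.93 to -2.71)) and Il1b, which encodes interleukin-1 beta, 4662 and 2442 CPM. The inflammatory list had a median of -0.95 (-1.11 to -0.80). The regulatory and tolerance-associated list had a like median, -0.96 (-1.14 to -0.85), and its members Cd274, the gene of the checkpoint ligand PD-L1, at 172 and 34.3 CPM, Socs3, a brake on cytokine signalling, at 444 and 81.5, and the inhibitory receptor gene Lilrb4a at 985 and 377 were all lower. Besides Ifit3 and Isg15, the largest deficits were those of Ifit1 (log2 ratio -7.14), Ifit2, Ifit3b, Slfn5, Ifi207, Herc6, Usp18 and Zbp1 (-4.62), all induced by interferon. Nfkbia, the inhibitor of NF-kappaB and a member of the dissociation stress list, was 1164 and 311 CPM, and that list's median was -0.48 (-0.52 to -0.42). Hif1a, the hypoxia regulator, was 274 and 133 CPM, whereas the hypoxia and glycolysis list as a whole had a median of 0.35 (0.12 to 0.45).

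Neutrophil-like cells came from cluster 1 (2658 untreated and 13 ConA cells) and cluster 21 (28 untreated and 476 ConA cells), so their values also compare these clusters. Camp was detected in 2.02% and 30.6% of thinned neutrophil-like cells (3.09% and 38.9% unthinned, 157 and 12 cells left out). Its background in B-like cells was 0.786% and 5.70%, at median depths of 2305 and 2834 UMIs against 2510.5 and 3080. The median log2 ratio over all well-expressed genes of the class was 0.13, and the oxidative phosphorylation list, at 0.21, lay at percentile 50.5.

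Monocyte and macrophage-like cells of the ConA library also had lower inflammatory genes. Cxcl2 was 497 and 65.5 CPM (log2 ratio -2.92 (-3.14 to -2.71)), the tumour necrosis factor gene Tnf 89.6 and 14.6 and the interleukin-18 gene Il18 132 and 36.4. The complement factor B gene Cfb was 152 and 8.37 CPM. The inflammatory list had a median of -0.99 (-1.13 to -0.81) and the regulatory and tolerance-associated list one of -0.63 (-0.85 to -0.36). In the latter, Lgals9, which encodes galectin-9, was 408 and 101 CPM, and Socs3 201 and 66.6. Axl, a receptor for the uptake of dead cells, was 87.0 and 20.02 CPM, while the complement and efferocytosis list as a whole had a median of -0.01 (-0.24 to 0.11).

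Higher in the ConA cells of this class were Hpgd, which breaks down prostaglandins (34.5 and 172 CPM, log2 ratio 2.32 (2.14 to 2.50)), the lipid transporter family gene Abca9 (36.4 and 120.5), the collagen-binding integrin gene Itga1 (34.5 and 103), Serpinb10 (50.01 and 143) and Pid1 (457 and 1199). Rbpms, Sntb1, St8sia4, Tmem150b and Ldlrad3 had log2 ratios from 1.38 to 1.75. The largest deficit was that of Spon1, a secreted matrix protein gene (284 and 2.55 CPM), which also led the untreated cluster M2. The interferon-induced Slfn4, Ifit2, Oasl1, Phf11d and Ifi206 and the surface protein gene Ly6a followed, with log2 ratios from -5.23 to -3.90.

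The Kupffer cell identity list had 4 measured members of 16 and a median of -0.67 (-0.90 to -0.58). Of them Id1 was 81.6 and 25.5 CPM and Id3 144 and 72.1, both transcriptional regulators, while the Kupffer cell lectin gene Clec4f stayed below 1 CPM over all cells of either library. The lipid-associated macrophage list had a median of -0.06 (-0.10 to 0.04). MHC class II genes had a median of -0.23 (-0.32 to -0.20), which turned to 0.10 without doublet removal. C1qb (log2 ratio -1.16) and the cathepsin gene Ctsl (-0.26) turned to 1.81 and 1.18 in the same setting. The untreated cells came chiefly from clusters M0, M1 and M2 (986, 747 and 706 cells) and the ConA cells from cluster M3 (4 untreated and 388 ConA cells).

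In B-like cells, 3 genes met the rule for naming in the higher direction. They were the heat-shock protein gene Hsph1 (13.8 and 57.9 CPM, log2 ratio 2.07 (1.80 to 2.35)), the Hsp70 to Hsp90 co-chaperone gene Stip1 (35.2 and 79.2) and the carboxypeptidase gene Cpm (109 and 226). The 10 genes named in the lower direction, Ifit3, Ifit3b, Rtp4, Irf7, Ifit2, Oasl2, Oasl1, Mx1, Isg15 and Slfn5, are all induced by interferon, with log2 ratios from -7.13 to -3.47. The list of B cell activation and germinal centre genes had a median of 0.03 (-0.08 to 0.16). In it Bcl6, the germinal centre regulator, was 67.1 and 110.4 CPM, the activation marker gene Cd83 132 and 184 and the growth regulator gene Myc 52.0 and 35.4. MHC class II genes had a median of -0.19 (-0.22 to -0.16), with the protease gene Ctss at 712 and 431 CPM and the class II transactivator gene Ciita at 226 and 290.1. The cell cycle list had a median of 0.28 (0.20 to 0.43) over 6 measured members. Clusters 0 (2945 untreated and 42 ConA cells) and 2 (49 untreated and 2552 ConA cells) held most B-like cells. Haemoglobin RNA was higher in the ConA library in these cells, with Hbb-bs at 1453 and 6248 CPM and a median of 2.02 (1.98 to 2.08) for the red cell list, and 3 of the 4 measured members of the 12 on the hepatocyte list were lower and 1 was more than 2-fold higher (median -1.22 (-1.38 to -1.03)).

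Naive T-like cells had 6 genes named as higher in the ConA library. Hsph1 was 16.2 and 73.4 CPM (log2 ratio 2.18 (1.83 to 2.54)), Ctla2a, a cathepsin inhibitor gene, 14.7 and 67.1, the transcription factor gene Myb 17.7 and 53.4, the TGF-beta signal transducer gene Smad3 41.4 and 90.3 and the kinase-like scaffold gene Peak1 88.1 and 191. Il2rb, a receptor chain for interleukins 2 and 15, was 73.0 and 169.6, but its log2 ratio of 1.22 became -0.11 without doublet removal. Socs3 was 120.3 and 29.4 CPM, and the other 9 genes named as lower, Ifit3, Ifit1, Isg15, Rtp4, Oasl2, Slfn5, Oasl1, Irf7 and Xaf1, were interferon-induced. The naive and circulating T list had a median of -0.25 (-0.30 to -0.19). In it Klf2, which keeps T cells in circulation, was 1222 and 840.2 CPM. The integrin gene Itgae was 50.1 and 24.5, and the type 2 regulator gene Gata3 48.0 and 88.0. The immediate early genes Fos and Zfp36 were 247 and 132 CPM and 271 and 133 CPM, and the dissociation stress list had a median of -0.36 (-0.41 to -0.32). The cytotoxic effector list, at 0.35 (0.25 to 0.48), turned to -0.08 without doublet removal, and of its member Ccl5 (102 and 422 CPM) 71.04 and 233 CPM was estimated as free RNA. Untreated cells lay chiefly in clusters T6 and T9 (772 and 527 cells) and ConA cells in T2 and T3 (955 and 923 cells).

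In Zbtb16-high T cells, the 10 genes with the largest excess in the ConA library were, among ConA cells, highest in cluster T16, which held 3.10% of the untreated and 18.0% of the ConA cells of the class. Over the class Il23r, the receptor for interleukin-23, was 12.0 and 80.1 CPM (log2 ratio 2.74 (2.22 to 3.31)), the interleukin-1 receptor gene Il1r1 10.9 and 110 and the growth factor receptor gene Igf1r 24.7 and 199. The ubiquitin ligase gene Marchf3 was 17.6 and 156 CPM, the metalloprotease gene Adam12 22.8 and 99.95, the selenium carrier gene Selenop 20.2 and 70.8 and the AP-1 gene Jun 48.3 and 182. Ldlrad4, Actn2 and Plcb4 had log2 ratios from 1.81 to 1.996. Within T16 (20 untreated and 279 ConA cells) Il23r was 429 and 408 CPM and Il1r1 388 and 553, whereas in the untreated cells of T7 and the ConA cells of T0, most cells of the class in each library, Il23r was 0 and 1.65 CPM and Il1r1 0 and 3.78. Between those clusters Jun, at 48.7 and 135 CPM, and Ldlrad4, at 36.9 and 123, also differed, as did Marchf3 (3.53 and 18.4), Igf1r (7.85 and 18.2), Plcb4 (16.5 and 32.1), Adam12 (17.7 and 29.5), Selenop (19.2 and 31.7) and Actn2 (9.42 and 15.4). The list of T helper cytokines and regulators had a median of 0.57 (0.49 to 0.69) (percentile 99.95), with the regulators Bcl6 at 33.3 and 80.5 CPM, Maf at 178 and 298, Tbx21 at 221 and 341 and Gata3 at 140.4 and 205. The cytokine genes Ifng and Il4 were 83.9 and 99.8 CPM and 117 and 107 CPM.

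The protease gene Gzmb, a mediator of target cell killing, was 458 and 122 CPM in Zbtb16-high T cells (log2 ratio -1.90 (-2.04 to -1.77)). Il7r, the receptor for the survival cytokine interleukin-7, was 163 and 342 CPM. The NKT identity list had a median of -0.04 (-0.10 to 0.04), with the residency chemokine receptor gene Cxcr6 at 513 and 649.9 CPM and Il2rb at 1378 and 1080. The oxidative phosphorylation list had a median of -0.34 (-0.42 to -0.28), with the cytochrome c gene Cycs at 244 and 138 CPM. The genes named as lower, Ifit3, Ifi27l2a, Isg15, Ifit3b, Rtp4, Oasl2, Ifit1, Irf7, Oas3 and Usp18, were interferon-induced, with log2 ratios from -4.43 to -2.75. Clusters T7 (611 untreated and 35 ConA cells), T0 (14 untreated and 1238 ConA cells) and T16 (20 untreated and 279 ConA cells) made up the class. Il23r was detected in 0.786% and 4.50% of thinned cells (1.71% and 8.76% unthinned, 9 and 18 left out), with a background of 0.0262% and 0.280% in B-like cells at median depths of 4064 and 3576 against 2305 and 2834 UMIs.

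NK-like cells of the ConA library had less Gzmb, 1597 and 614 CPM (log2 ratio -1.38 (-1.46 to -1.30)), and more Klrg1, a receptor of mature NK cells, 69.8 and 137 CPM. Itga1, a marker of liver-resident innate lymphocytes, was 5.87 and 52.2 (log2 ratio 3.15 (2.47 to 3.90)), and Cd7 130.3 and 308. The chemokine gene Ccl5 was 6228 and 9246 CPM. The cytotoxic effector list as a whole had a median of -0.13 (-0.17 to -0.08) and the tissue residency list one of 0.43 (0.31 to 0.54). Hypoxia and glycolysis genes had a median of -0.39 (-0.51 to -0.30), with the glycolytic enzyme genes Gapdh at 540 and 320.1 CPM and Pgk1 at 87.2 and 51.8, and oxidative phosphorylation genes one of -0.36 (-0.43 to -0.29). Also named as higher were Hsph1 (22.0 and 85.9 CPM), Ldlrad4, Inpp4a and Nipal3 and the T cell receptor complex genes Cd3g, Cd3d, Cd3e and Trac. Of the Cd3g level (36.1 and 110.5 CPM), 20.5 and 61.7 CPM was estimated as free RNA. The genes named as lower were interferon-induced, led by Ifit3, Rtp4, Slfn5 and Ifi204. Of these levels a part was estimated as free RNA, 48.1 and 1.39 CPM of Ifit3, 29.6 and 3.16 of Rtp4 (147 and 13.3), 83.2 and 7.88 of Slfn5 (101 and 8.18) and 49.1 and 2.82 of Ifi204 (69.6 and 4.43), and of Ifi27l2a (263 and 37.8 CPM) 223 and 35.2 CPM was estimated as free RNA. Gzmb was detected in 68.0% and 36.5% of thinned NK-like cells (87.4% and 61.5% unthinned, 50 and 28 left out) against 4.48% and 4.02% of B-like cells, at median depths of 3329 and 3258 against 2305 and 2834 UMIs. NK-like cells lay chiefly in cluster T5 (798 untreated and 24 ConA cells) and cluster T1 (131 untreated and 868 ConA cells).

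ILC1-like cells showed the same direction for Gzmb, at 5298 and 1193 CPM, and for Gzma, another protease gene of cytotoxic granules, at 5742 and 3105. Il7r was 59.1 and 187 CPM, the transcription factor gene Runx1 374 and 925 and the costimulatory receptor gene Cd28 33.8 and 97.9. ILC1-like cells were held by cluster T10 (320 untreated and 200 ConA cells) and cluster T8 (42 untreated and 558 ConA cells). Cluster T10, 88.4% of the untreated and 26.4% of the ConA cells of the class, was led by Gzmb, with Gzma among its 10 leading genes. Those of T8 held neither, so these values also compare clusters.

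CD8 T-like cells of the untreated library, 112 cells, carried more checkpoint receptor RNA than the 1335 of the ConA library. Pdcd1, the gene of PD-1, was 197 and 31.0 CPM (log2 ratio -2.67 (-3.08 to -2.25)), Havcr2, the gene of TIM-3, 219.7 and 25.2, Lag3 285 and 64.5, Ctla4 568 and 147 and Tigit 116 and 26.1. The checkpoint and exhaustion list had a median of -1.08 (-1.42 to -0.99) and the cytotoxic effector list one of -0.60 (-0.67 to -0.44), with the chemokine gene Ccl4 at 2261 and 674 CPM and Gzma at 417 and 906. Higher in the ConA cells were the residency integrin gene Itga1 (80.8 and 368 CPM), Tbx21, which encodes the type 1 regulator T-bet (96.0 and 294), the interleukin-18 receptor gene Il18r1 (42.9 and 136) and Eya2 (15.2 and 92.7). The gamma-delta receptor gene Trdc was 546 and 17.3 CPM. Of the untreated cells 74 lay in cluster T17, which held 147 of the ConA cells, whereas 823 ConA cells lay in cluster T4 and 365 in T14, so the class compares different clusters. Lag3, Pdcd1 and Ctla4 were among the 10 leading genes of T17. As a share of all cells T17 was larger in the ConA library (0.482% and 0.955%, log2 ratio 0.99 (0.57 to 1.41)). The lower class level thus does not mean that checkpoint-rich cells were fewer there.

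In Treg-like cells, all in cluster T12, 9 of the 13 measured members of the Treg suppression list were lower in the ConA library and 4 higher (median -0.32 (-0.58 to -0.09)). The lineage regulator gene Foxp3 was 142 and 69.0 CPM (log2 ratio -1.04 (-1.52 to -0.58)), the high-affinity interleukin-2 receptor gene Il2ra 109 and 57.7 and Ikzf2 1134 and 752, while Tbx21 was 70.6 and 159 and Gata3 174 and 241. Foxp3, Il2ra and Ikzf2 are also among the markers that name the class, and at resolution 2 the class held 96 and 46 cells.

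**Figure D3:**
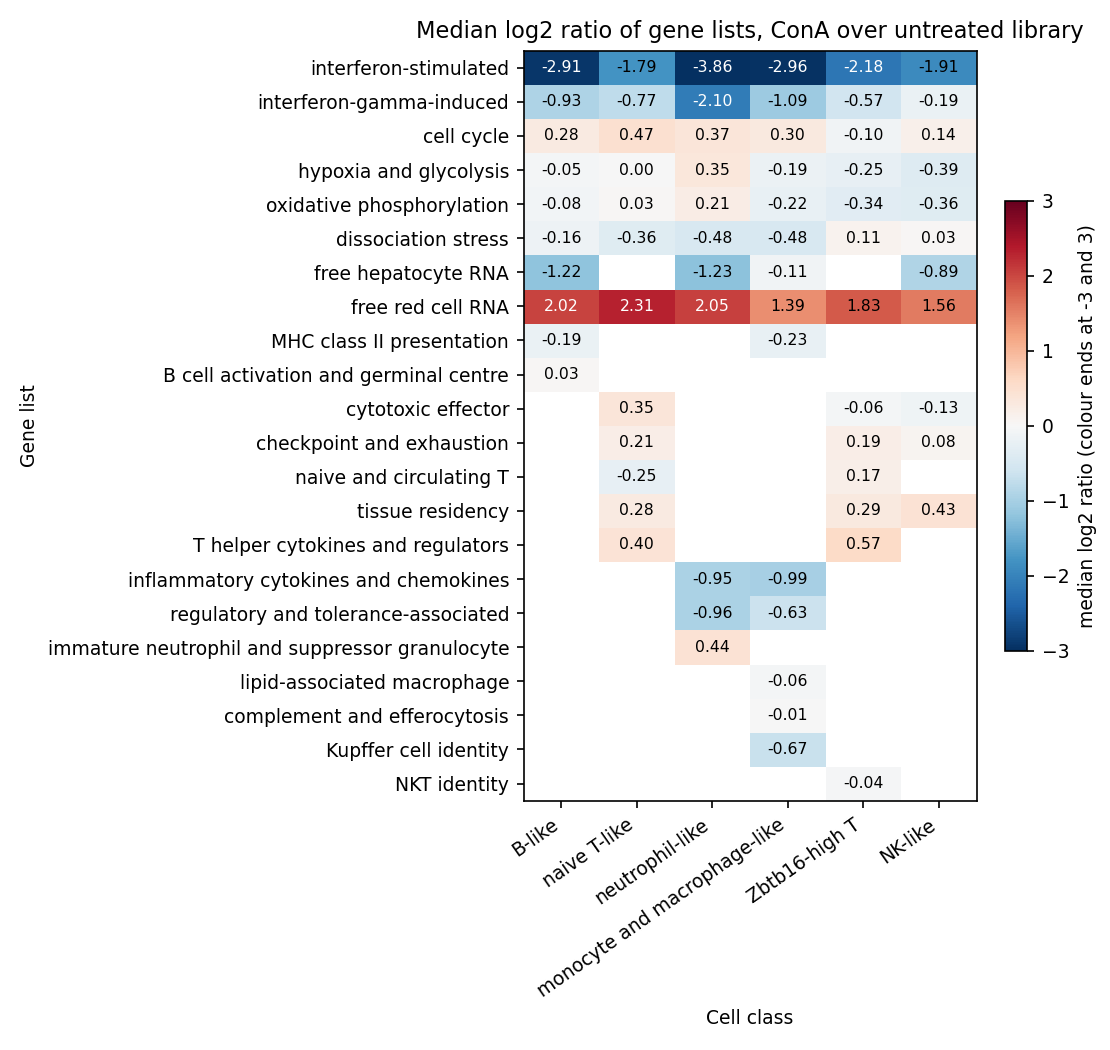
Median log2 ratio (ConA over untreated) of each gene list in the 6 classes with the most cells, with colour ends at -3 and 3 and blanks where a list was not described or had too few measured members. Both interferon lists are negative in all 6 classes, and the free red cell RNA list is positive in all 6.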

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

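The alternatives with fewer doublets removed (0.4% per 1000 barcodes), with library-dependent genes left out of the clustering and with estimated free RNA subtracted were chosen after the data were seen, and the others before. The 6 headline shares and the 6 headline medians of the interferon-stimulated list, those of the classes with the most cells, kept their direction under each alternative that gave a value. The list median ran from -3.66 to -2.32 in B-like, -2.04 to -1.24 in naive T-like, -4.11 to -3.18 in neutrophil-like, -3.27 to -2.61 in monocyte and macrophage-like, -2.33 to -1.79 in Zbtb16-high T and -2.25 to -1.52 in NK-like cells. Values below left the counting interval of the reported value or changed direction, and the cause was not tested except where stated.

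For shares, the log2 ratio of monocyte and macrophage-like cells was -2.37 with a minimum of 1000 UMIs. Without doublet removal it was -2.37, that of naive T-like cells 0.31 and that of neutrophil-like cells -2.22. At resolution 0.5, Zbtb16-high T cells had 1.04 and naive T-like cells 0.39. By highest marker score naive T-like cells had 0.23. With each library clustered alone, B-like cells had -0.16, Zbtb16-high T cells 1.12 and naive T-like cells 0.40. At the lower doublet rate of 0.4%, B-like cells had -0.38, monocyte and macrophage-like cells -2.32 and neutrophil-like cells -2.26. Of 17 shares 15 stayed within their intervals at resolution 2, 16 at 5% and 14 at 20% mitochondrial UMIs. Marker scores gave no value for Zbtb16-high T cells, which have no marker list, and resolution 0.5 gave none for Treg-like cells. Clustering each library alone gave none for CD4 T, gamma-delta T, plasma and Treg-like cells, which had no named cells in 1 library.

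Other shares left their intervals by larger distances. CD4 T-like cells, at 5.88 as reported, had 2.08 at 20% mitochondrial UMIs, 2.03 at resolution 2, 1.503 at resolution 0.5 and 1.498 by marker scores. Gamma-delta T-like cells, at 6.22, had 4.28 without doublet removal, 3.68 at 0.4% doublets, 4.70 at resolution 0.5 and 2.40 by marker scores. CD8 T-like cells, at 3.57, had 2.25 by marker scores and 4.13 with each library clustered alone. Plasma-like cells, at 5.37, had 2.27 without doublet removal and 2.57 by marker scores, and cDC1-like cells, at 1.59, had 0.88 without doublet removal, 0.71 at 0.4% doublets and 0.38 by marker scores. No share whose reported interval excluded 0 changed direction. Treg-like cells, at -0.08, had -1.12 at 20% mitochondrial UMIs, -1.06 at resolution 2 and 0.78 by marker scores, and cDC2-like cells, at -0.22, had 0.27 at 0.4% doublets. The cause was not tested.

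For the interferon-stimulated list, a constant of 1 CPM gave medians of -3.66 in B-like, -2.04 in naive T-like, -4.11 in neutrophil-like, -3.27 in monocyte and macrophage-like and -2.25 in NK-like cells, and 20 CPM gave -2.32, -1.24, -3.18, -2.61 and -1.52 in the same order and -1.79 in Zbtb16-high T cells. A larger constant draws every ratio toward 0 by construction.

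Without doublet removal, 7 of 574 gene values changed direction. They were Il2rb -0.11, Ccl5 -0.0648 and Nkg7 -0.12 in naive T-like cells, Ctsl 1.18 and C1qb 1.81 in monocyte and macrophage-like cells, Gzma 0.0175 in Zbtb16-high T cells and Hmgb2 -0.0781 in Treg-like cells. The cytotoxic effector list in naive T-like cells (-0.0804) and the MHC class II list in monocyte and macrophage-like cells (0.10) also changed direction, and the cause was not tested. Thinned to 1000 UMIs, 7 of 565 values changed direction, Runx3 -0.0433 in naive T-like cells, Sh2d1a -0.0575 in Zbtb16-high T cells, Tubb5 0.0393 in NK-like cells, Hmgb2 -0.0898 in CD8 T-like cells, H2-Oa 0.0935 in pDC-like cells and Hmgb2 -0.0350 and Atp5g1 0.29 in Treg-like cells.

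With free RNA subtracted, Hbb-bs became -1.80 and the red cell list -5.36 in monocyte and macrophage-like cells, Hba-a2 -0.20 in Treg-like cells and the tissue residency list -0.14 in naive T-like cells. The cell cycle list in Zbtb16-high T cells became 0.0385 without a minimum for members and 0.0907 with each cell weighted equally, and the cause was not tested. No gene value changed direction with cells weighted equally, with median of ratios scaling or at 5% mitochondrial UMIs, where 513, 532 and 536 of 574 stayed within their intervals. Without doublet removal 447 of 574 did and 120 left them without changing direction, thinned to 1000 UMIs 380 of 565 did and 178 left them, and with free RNA subtracted 487 of 563 did and 74 left them. Depth sets detection, and 505 of 702 detection shares left their intervals without thinning.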

Other observations

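Dendritic cells and non-classical monocytes also differed between the libraries. In pDC-like cells, all in cluster 11 (463 untreated and 548 ConA cells), the transcription factor gene Runx1 was 130 and 322 CPM and the stress kinase gene Map2k6 15.6 and 63.9. Sct, the gene of the hormone secretin, was 50.5 and 3.70 CPM and Slfn5, induced by interferon, 610.2 and 40.7. The cell cycle list had a median log2 ratio of 0.78 (0.54 to 1.03) over 6 measured members of 14, all 6 higher. Its members with at least 50 CPM, Tubb5 and Hmgb2, had smaller log2 ratios of 0.53 and 0.27. The inflammatory list had a median of -1.26 (-1.48 to -1.08). In cDC2-like cells, MHC class II genes had a median of 0.35 (0.31 to 0.38), with the class II transactivator gene Ciita at 247 and 538 CPM and the peptide-loading gene H2-DMb2 at 55.4 and 218. The monocyte genes Ly6c2 (1728 and 55.8 CPM) and Fcgr1 (300.2 and 0) were lower. The untreated cDC2-like cells lay chiefly in cluster M6 (214 untreated and 6 ConA cells) and the ConA cells in M8 (24 untreated and 154 ConA cells), so these values also compare clusters.

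Non-classical monocyte-like cells had more Hpgd, which breaks down prostaglandins, in the ConA library (199.8 and 517 CPM), and more Zbtb16 (82.3 and 209). The chemokine gene Cxcl2 was 292 and 45.1 CPM, Il1b 262 and 80.6 and Cd274, the gene of PD-L1, 285 and 85.4. They lay in cluster M4 (291 untreated and 4 ConA cells) and cluster M7 (8 untreated and 172 ConA cells). Of the RNA over all cells of a library, the 4 haemoglobin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 summed to 10600 and 54010 CPM, and the antibody light chain gene Igkc was 2080 and 15380 CPM.

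The tests of exchanged labels, of the denominator and of the dissociation response, and the free RNA subtraction, were chosen only after the result was seen. Interferon-stimulated genes were lower in the ConA library in each of the 12 classes measured. Free RNA of interferon-high cells in the untreated library is argued against as the whole cause, since after its estimate was subtracted the median of the list medians of 5 classes was -2.26. If the libraries carried each other's label, sex-linked genes could show it only where the mice differed in sex, but Xist was 0.0724 CPM in the ConA library, Y-linked genes were present in both and the labels give no sex, so exchanged labels cannot be told apart from the labels as given. An effect of repeated ConA, or an interferon response of the untreated mice for another reason, stays open and untested, because treatment, mice and preparation are the same split.

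CD8, CD4 and gamma-delta T-like cells together were 17.4-fold more frequent in the ConA library. If untreated cells of these types had been placed in other clusters, clustering each library alone could have restored them. The untreated share was then 0.0327 times the ConA share, a 30.6-fold excess. That value cannot decide the question, because CD4 T-like and gamma-delta T-like cells had no named cells in 1 library there. With the unnamed untreated T, NK and innate lymphoid clusters counted in, the untreated share was 0.223 times the ConA share. By marker scores, which use no clusters, it was 0.253 times. These last ratios argue against placement as the whole cause, while the size of the excess depended on it and was 3.95-fold by marker scores. The gamma-delta gene Trdc was also higher in untreated than in ConA CD8 T-like cells. Summed over T, NK and innate lymphoid cells, the CD8 and CD4 T markers measured were only 0.930 to 2.77 times as high in the ConA library. With the cells as clustered, fewer neutrophils and monocytes cannot account for the excess alone either. The log2 ratio among T, NK and innate lymphoid cells was then 3.13 (2.87 to 3.40). That ratio rests on the same cluster placement, so it cannot decide what placement and fewer phagocytes do together. All T, NK and innate lymphoid cells were 1.98-fold more frequent in the ConA library, against the 3.95-fold excess by marker scores. The joint effect was not tested and stays open. More CD8, CD4 and gamma-delta T-like cells in the liver after repeated ConA stays open too. So do differences between the mice or preparations, which were not tested.

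In the 6 classes with the most cells, the heat-shock genes Hsph1 and Stip1 were higher in the ConA library. The cold-induced genes Cirbp and Rbm3 were lower in it. Log2 ratios were 1.54 to 2.72 for Hsph1 and -1.61 to -0.63 for Cirbp. The Hsph1 value of 2.72 (1.41 to 4.11), in neutrophil-like cells, rests on low levels of 1.30 and 8.58 CPM. A stronger dissociation response stays open, because the median of the dissociation stress list was below 0.25 in 6 of these 6 classes but its members went both ways, with its heat-shock gene Hspa8 (0.24 to 0.83) higher in the 6 classes, Dnajb1 higher beyond its counting interval in 4 of them, and Dusp1 and Nfkbia, for example, lower in B-like cells. A higher temperature of the mice or cells would raise other targets of heat-shock factor 1, whose median was above 0.25 in 3 of the 6 classes (0.36 in B-like, 0.54 in naive T-like and 0.52 in neutrophil-like cells) and below it in the other 3 (0.19 in monocyte and macrophage-like, 0.08 in NK-like and -0.01 (-0.05 to 0.21) in Zbtb16-high T cells). That count met the bound set beforehand against a higher temperature, but a check against the counting intervals, added after the count was seen, left 2 of those 3 medians not separable from 0.25 (upper limits 0.30 in monocyte and macrophage-like and 0.26 in NK-like cells), so this explanation cannot be told apart from others. A febrile or stress response to ConA itself may underlie the pattern too and was not tested.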
